A study of Mus musculus with 6 samples.

How the data were processed

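Gene expression was measured in mouse CD4 T cells with Affymetrix arrays of the 3' in vitro transcription type, on which each probe set reads a short stretch of a transcript, mostly near its 3' end. The 6 samples form 6 groups of 1 array each, from 2 genotypes and 3 cell populations. Per the labels' protocols, total RNA was extracted with Trizol and biotinylated cRNA was prepared by the standard Affymetrix procedure. The deposited values are array intensities on a linear scale, called signals here, and were made with MAS5, per the submitters' processing notes. The version of MAS5, its settings and an annotation build are not given in the sources used here, so no genome coordinates are printed. In each deposited array the mean signal after trimming 2% of the probe sets at each end was 500, so the arrays had been brought to a common trimmed mean before they were deposited. Such scaling equalises the average brightness and leaves differences in the dim range, where the fold between 2 dim signals is mostly noise.

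The table holds 45101 probe sets, of which 64 are control probe sets and were used only as quality measures. Of the other 45037, 34945 carry 1 gene symbol in the platform annotation, 932 carry several and 9160 carry none; probe sets with several symbols or none were not named. The Entrez identifiers of 34741 of the 34945 matched a RefSeq gene table of the GRCm38.p6 assembly, which was used for names only, and 0 symbols changed. The 18193 genes that resulted were each represented by the probe set with the highest mean log2 signal over the 6 arrays. The text names 236 gene and population combinations by the rule stated further on, 105 of which had several probe sets above the floor. In 36 of these, at least 1 other probe set went the opposite way. Others kept the direction at a much smaller size, such as those of Ntn1 in regulatory cells and Bub1 in memory cells.

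A floor was set at the pooled 40th percentile of all non-control probe sets over the 6 arrays, a signal of 47.6. Signals below it were raised to it before log2 was taken, and a gene below it on both arrays of a comparison was left out of that comparison. A fold against an array below the floor is a lower bound and is written as "at least". Log2 folds are the array labelled Furin cKO over the control array of the same population. With 1 array per group there is no replicate check within a population: no spread between animals is known, no p-value is given there, and a count of genes past 2-fold describes these 2 arrays. For arrays, their number limits the precision.

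Gene lists were described by the median log2 fold of their measured members. The median was placed among the medians of 10000 random lists of the same size, drawn with replacement from genes of the same mean signal in 20 signal bins. The central 95% of those medians is called the random range, and a list of fewer than 3 measured members was given no percentile. The percentile describes how a list stands on these arrays and is not a p-value; about 5% of lists lie outside by chance, and more where members share a regulator. There were 39 lists, covering T cell programmes, metabolism, stress, convertases and markers of other cell types; members with no probe set in the annotation used here were not analysed here.

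Changes in different populations were compared by the number of genes past 2-fold in the same direction, beside the number that independent lists would share, and by the correlation of log2 folds across genes, which are not independent replicates. The 3 genotype comparisons share no array. A linear model with population and genotype as factors was fitted to all 6 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and Benjamini-Hochberg adjustment over 15811 genes above the floor on some array. It has 2 residual degrees of freedom. Its p-values for genotype measure how far the genotype difference varied between populations, not between animals, and the labels do not say whether the populations came from the same animals.

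The genes named are Furin; the 8 largest differences each way per population among genes above the floor on both arrays, with the brighter array at or above the pooled 60th percentile (a signal of 144.8); the 4 largest lower bounds each way; up to 4 members of each list outside its random range; the 8 genes each way that kept 1 direction in the 3 populations with the largest smallest fold; the top 6 genes each way of the limma population contrasts with label markers; and members named to describe a list. Clone or predicted names, such as those with Rik or with Gm and digits, were left out of these rankings of single genes. This rule, the 39 lists, the floor, the comparisons with their tests and all alternatives but the floor of each array and the exchange of memory labels were fixed before the data were examined. Further lists and some tests of explanations were added later, and the closing observations name them. Alternatives were quantile normalization, centring on the median, cyclic loess, floors at the 20th and 60th percentiles, the mean of a gene's probe sets, a floor at each array's own 40th percentile, an exchange of the genotype labels of the memory arrays, and for limma also fits without each population, a trended robust prior and no filter.

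The steps were tested on simulated data with normal noise. Except in the last simulation, its SD was the median absolute deviation of the log2 folds of each pair, scaled to an SD. It was the same at every signal, so the larger scatter of dim genes was not simulated and the counts of unchanged genes may be too low. The changed genes were drawn from those above the floor on the control array, with the brighter array at or above 144.8. The shares recovered thus do not hold for dim genes. Of 100 genes with a simulated log2 fold of 1.5, 99 passed 2-fold in activated cells, 86 in memory cells and 94 in regulatory cells. Unchanged genes passed 2-fold in 0 of 10404 cases for activated cells, 391 of 13018 for memory cells and 24 of 13393 for regulatory cells. For genotype averaged over populations, the changed genes were above the floor on all 6 arrays and were given the same fold in each population. Limma recovered 60 of 100 genes changed by 1.5 and 91 of 100 changed by 3 on the log2 scale, with 0 of 14770 unchanged genes called. For regulatory minus memory, the last simulation, limma called 89 of 100 genes changed by 3. The noise there was not set to the observed spread of the pairs. That share therefore does not measure how many such genes would be called on the real arrays.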

Results

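Furin is a proprotein convertase, an enzyme of the secretory pathway that cuts precursors such as that of TGF-beta 1 into their active forms. The series asks what its loss does to T cells. CD4 T cells came from C57BL/6 mice of 10 to 11 weeks with loxP-flanked Fur alleles, either without Cre (control) or with Cre under the Cd4 promoter, which acts during thymocyte development (Furin cKO, conditional knockout). Naive CD44-negative cells were stimulated for 2 days on plate-bound antibodies against CD3 and CD28, each at 5 µg/ml, while CD44-positive memory cells and CD25-positive, FoxP3-positive regulatory cells were taken without culture. Each of the 6 combinations was hybridised to 1 array, so no value below has a replicate or an SD.

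The activated arrays stood apart from the others in technical terms. The share of probe sets at or above the floor was 49.4% and 49.8% on the activated arrays, 62.6% and 65.2% on the memory arrays and 65.8% and 67.4% on the regulatory arrays, control first. The hybridisation control bioB gave 1059 and 1189.8 on the activated arrays, 6728 and 4915 on the memory arrays, and 3086 and 3057 on the regulatory arrays. The 3' to 5' signal ratio of beta-actin, a measure of RNA and labelling quality, was 1.22 and 1.24, 1.93 and 1.56, and 1.35 and 1.36 in the same order. Population and hybridisation batch cannot be told apart for differences between populations. Within a population the log2 signals of both genotypes correlated across 9446 genes at 0.992 for activated, 0.962 for memory and 0.981 for regulatory cells.

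The targeted gene itself did not separate the genotypes in a uniform way. The only Furin probe set (Entrez Gene 18550) read 515.8 on the control and 468.3 on the Furin cKO array of activated cells, and 547.2 and 410.0 in regulatory cells. In memory cells it read 647.4 on the control array and 2203 on the array labelled Furin cKO, 3.40-fold higher, the opposite of a loss. The position of this probe set in the gene is not given in the sources used here. The conditional allele is known to remove an early coding exon, and a probe set outside the deleted part checks nothing about the deletion. The signal in memory cells thus cannot decide whether the memory labels are right. The arrays are therefore called by their labels, and each direction below rests on those labels. The list of 6 measured convertases, Furin among them, had median log2 folds of 0.00, -0.03 and -0.03 in activated, memory and regulatory cells, all inside the random range; the means had the opposite sign in memory (0.37) and regulatory cells (0.01). Genes of convertase substrates had medians of -0.06 and -0.10 in activated and memory cells, also inside.

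**Figure D1:**
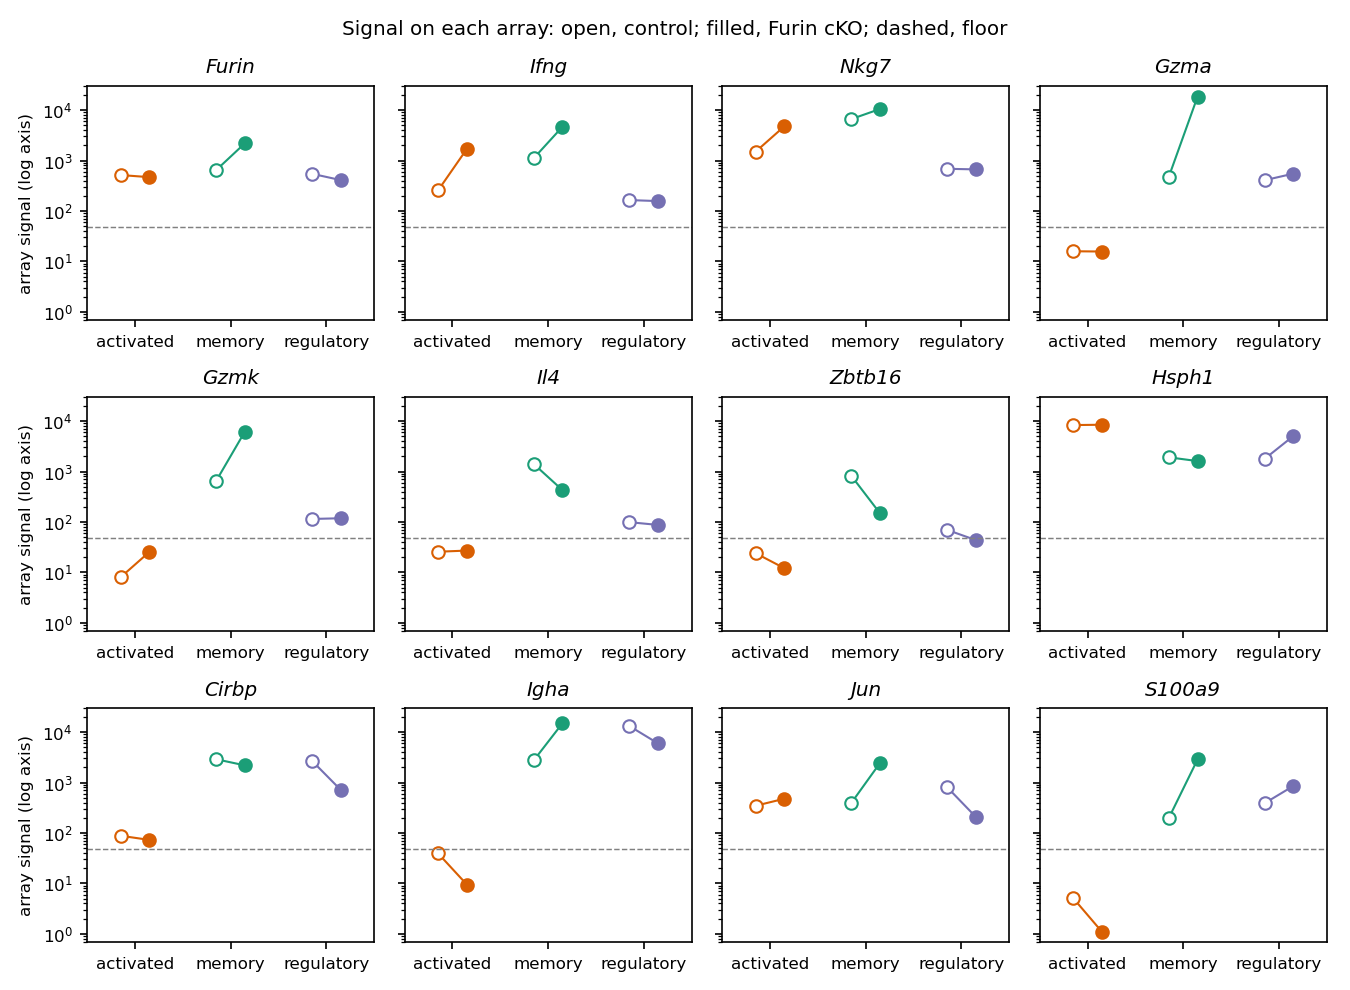
Array signal (log axis) of 12 genes on the 6 arrays, open circles for control and filled circles for the arrays labelled Furin cKO, joined within activated, memory and regulatory cells; the dashed line is the floor of 47.6, and each point is 1 array. Furin read higher on the labelled Furin cKO array only in memory cells, Ifng differed in activated and memory cells, and Gzma and Gzmk differed in memory cells.

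In activated naive cells the array labelled Furin cKO carried more transcript of type 1 and cytotoxic effector genes and less of the cholesterol pathway. Ifng, which encodes interferon-gamma, read 1695 against 256.6 on the control array, 6.61-fold higher, and Nkg7, a cytotoxic granule protein, read 4776 against 1499, 3.19-fold higher. Tbx21, the transcription factor that drives type 1 differentiation, read 2140.0 against 1208. Of 10756 genes measured, 42 were at least 2-fold higher and 40 at least 2-fold lower, and the median absolute deviation of the log2 folds, scaled to an SD, was 0.21.

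The type 1 effector list had 10 of 14 measured members higher, 4 of them at least 2-fold (Ifng, Ccl5, Ccl3 and Ccl4), and its median log2 fold of 0.28 lay above all 10000 random lists. The chemokines Ccl5, Ccl3 and Ccl4 were 2.44-fold, 2.23-fold and 2.04-fold higher. The cytotoxic list had a median of 0.63, also above all random lists, with 6 of 8 members higher, 3 of which (Klrg1, Ctsw and Klrc1) were below the floor on the control array and enter as lower bounds. Among members above the floor on both arrays, the largest after Nkg7 was Gzmb (granzyme B) at 1.90-fold. The perforin gene Prf1 read 52.3 on the control and 48.3 on the Furin cKO array. Secreted cytokines and chemokines had a median of 0.39 above all random lists, with 15 of 21 members higher and 8 of them at least 2-fold. Beside the genes above these included Ccl1 at 3.35-fold, Xcl1 at at least 2.67-fold, and the cytokine genes Il3 (265.1 and 551.9) and Csf2 (562.3 and 1163). NF-kB pathway genes were higher for 12 of 13 members with a median of 0.22, above all random lists, led by Icam1 at 1.41-fold.

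Cholesterol synthesis genes were lower for 13 of 15 members, with a median of -0.26 below all random lists. Mvd and Pmvk, enzymes of the mevalonate pathway, were 1.58-fold and 1.39-fold lower, and Dhcr7, which makes the last step of cholesterol synthesis, 1.33-fold lower. Treg signature genes (median -0.12), cell cycle genes (-0.07), oxidative phosphorylation genes (0.08) and adhesion molecules (0.11) lay just outside their random ranges. Of 7 alternatives the Treg signature stayed outside in 1, the cell cycle in 4, oxidative phosphorylation in 5 and adhesion in 6, the last with medians from 0.05 to 0.23. Outside the lists, the largest differences were ranked among genes above the floor on both arrays, clone or predicted names aside. Those upward were in Zdhhc12 (200.8 against 55.7), the membrane protein gene Marveld1 (3.57-fold), the tropomyosin gene Tpm2 (3.05-fold, with another probe set lower), Ajuba (366.5 against 139.6) and Camta1 (2.57-fold). Those downward were in Cd5l (3.57-fold), the kinase Map2k6 (2.65-fold), the clock repressor gene Cry2 (79.9 against 200.1), Sntb1 (2.45-fold), the glycosyltransferase Gcnt1, Fcrl1 and Trpm6. Casp14 was at least 4.39-fold and Clip4 at least 3.69-fold higher, and Tfr2 at least 3.33-fold lower, with another Tfr2 probe set higher.

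Few markers of other cell types could be read in activated cells. The medians of B cell (0.06), plasma cell (-0.25) and myeloid and dendritic cell markers (-0.03) lay inside their random ranges, and granulocyte, erythroid and NK cell markers had 0 members above the floor. B cell markers, 4 of which were measured, lay above their range with cyclic loess (0.31 over 8 members) and with the floor at the 20th percentile (0.52 over 10) or of each array (0.43 over 8). Of 31 lists with a percentile, 9 lay outside their random range where chance gives 1.55. With floors at the 60th and 20th percentiles 17 and 472 genes were at least 2-fold higher and 9 and 444 lower, and with cyclic loess 115 and 83.

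**Figure D2:**
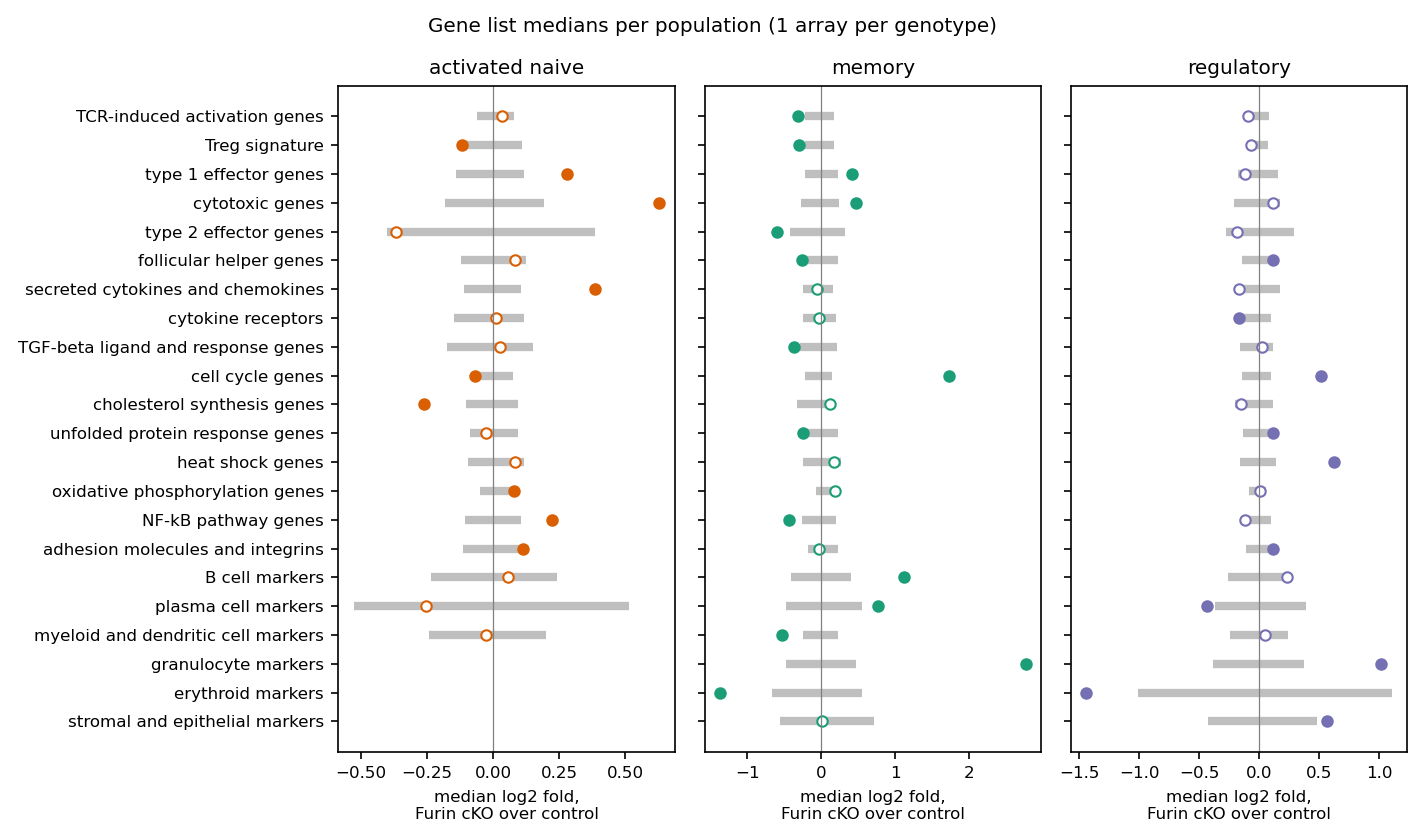
Median log2 fold (Furin cKO over control, x axis, scaled separately in each panel) of each gene list that left its random range in some population, 1 panel per population; grey bars give the central 95% of 10000 random lists, filled circles lists outside it and open circles lists inside it. Type 1 effector and cytotoxic lists lie to the right in activated (0.28 and 0.63) and memory cells (0.42 and 0.47), and cell cycle genes in memory (1.72) and regulatory cells (0.52).

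The memory arrays differed in more genes than the other pairs. Genes of dividing cells, granzymes and interferon-gamma read higher on the array labelled Furin cKO, and type 2 effector genes read lower. Gzma, which encodes granzyme A, gave 18470.5 against 479.7, 38.5-fold higher; Gzmk (granzyme K) was 9.49-fold, the chemokine receptor gene Cx3cr1 9.84-fold and Ifng 4.20-fold higher. Il4, the signature type 2 cytokine gene, was 3.29-fold lower and Zbtb16, which encodes the innate-like T cell factor PLZF, 5.54-fold lower. Of 14235 genes measured, 800 were at least 2-fold higher and 518 at least 2-fold lower, and the scaled median absolute deviation was 0.47. This pair also differed most in the technical measures, with a beta-actin 3' to 5' ratio of 1.93 on the control and 1.56 on the Furin cKO array and bioB at 6728 and 4915.

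All 27 measured cell cycle genes were higher, 17 of them at least 2-fold, and the median of 1.72 lay above all random lists. Rrm2, a subunit of ribonucleotide reductase, was 6.35-fold, Birc5 6.31-fold, the mitotic kinase gene Cdk1 5.00-fold and Bub1 4.83-fold higher. Another Bub1 probe set had a log2 fold of only 0.12. The proliferation marker Mki67 read 5261 against 1259.9. The replication helicase genes differed less, with Mcm6 at 5662 against 4418. On the same arrays granulocyte markers had a median of 2.76 and B cell markers a median of 1.12, both above all random lists, and plasma cell markers a median of 0.76 at percentile 99.7. With the floor at the 60th percentile these medians were 1.79, 0.45 and 1.44, and that of plasma cell markers was 1.57 with the floor at the 20th, all outside their ranges. S100a9 was 14.4-fold and S100a8 10.6-fold higher, Ms4a1 (CD20) 4.32-fold and the immunoglobulin genes Jchain and Igha 8.51-fold and 5.44-fold higher. Myeloid and dendritic cell markers were lower, with a median of -0.53 below all random lists. Of 19 members 15 were lower, including Siglech at 2.65-fold and H2-Ab1 at 2.35-fold. Siglech read 2943 and 1111 on the memory arrays against 66.3 and 95.3 on the regulatory arrays, control first. H2-Ab1 read 7618 and 3245.5 against 475.4 and 541.2, whereas Itgam of this list read 44.8 and 63.9 against 65.8 and 109.4. Both memory arrays thus carried marked signal of some such markers, and its share in the memory folds was not tested. Erythroid markers were lower with a median of -1.37 over 3 members. Members did not all follow: Mmp9 of the granulocyte list was 2.10-fold lower, and Ighm and Cd22 of the B cell list 1.39-fold and 1.60-fold lower. T cell receptor signalling components had a median of -0.03, inside the random range. NK cell markers (0.45 over 4 members) and stromal and epithelial markers (0.01) were also inside, and the CD8 gene Cd8b1 read 432.7 against 853.7.

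The type 1 effector list had a median of 0.42 and the cytotoxic list 0.47, at percentiles 99.96 and 99.98. They were lowest, though still outside, at 0.23 with quantile normalization for type 1 genes and at 0.27 with the floor at the 60th percentile for cytotoxic genes. In the type 1 list, 10 of 16 members were higher, with Il18r1 and Il18rap, which form the interleukin 18 receptor, 2.53-fold and 2.18-fold higher; Tbx21 read 3396 against 3616. In the cytotoxic list 9 of 12 members were higher, while the NK receptor genes Klrk1 (905.4 against 2116) and Klrc1 (335.3 against 1070.0) were more than 2-fold lower. Il2 read 1465 against 424.2. S1pr5, a sphingosine phosphate receptor of effector and NK cells, was at least 30.5-fold higher, and Esm1 13.4-fold.

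Type 2 effector genes had a median of -0.60 at percentile 0.09, with 6 of 9 members lower: Il17rb was 4.85-fold, Epas1 1.92-fold and the type 2 master regulator gene Gata3 1.69-fold lower, whereas Ccr4 read 343.4 against 169.6. NF-kB pathway genes had a median of -0.44, with Cd83 2.51-fold, Nfkb2 2.29-fold and Relb 1.96-fold lower. Another Nfkb2 probe set had a log2 fold of only -0.17. The list of TGF-beta ligand and response genes, which holds a furin substrate, had 14 of 15 members lower and a median of -0.37: Tgfbi was 4.03-fold, the integrin gene Itgae 2.14-fold, Tgif1 1.73-fold and Tgfb1 itself 1.64-fold lower. With the mean of a gene's probe sets this list lay inside its range (-0.20). Treg signature genes had a median of -0.30 with 16 of 18 members lower, including Il2ra (1.90-fold) and Nrp1 (1.69-fold). Another Il2ra probe set had a log2 fold of only -0.15. T cell receptor induced activation genes (-0.31), follicular helper genes (-0.27, led by Ascl2 at 3.51-fold) and unfolded protein response genes (-0.24, led by Herpud1 at 1.84-fold) lay below their random ranges too, though each was inside with at least 1 alternative. Other single genes lower included Ccdc102a (7.38-fold, with another probe set higher), Qpct (5.24-fold) and the gamma delta receptor segment Trgv1 (5.21-fold), with Tmem273 at least 8.56-fold and the lysosomal regulator gene Tfeb at least 7.91-fold lower.

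Of 36 lists with a percentile in memory cells, 15 lay outside their random range, against 1.8 by chance. With floors at the 60th and 20th percentiles 258 and 2219 genes were higher and 221 and 1531 lower. A simulation with normal noise at the scaled median absolute deviation of this pair passed 391 of 13018 unchanged genes. It left out the larger scatter of dim genes, so noise may account for more of the 2-fold genes than this.

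**Figure D3:**
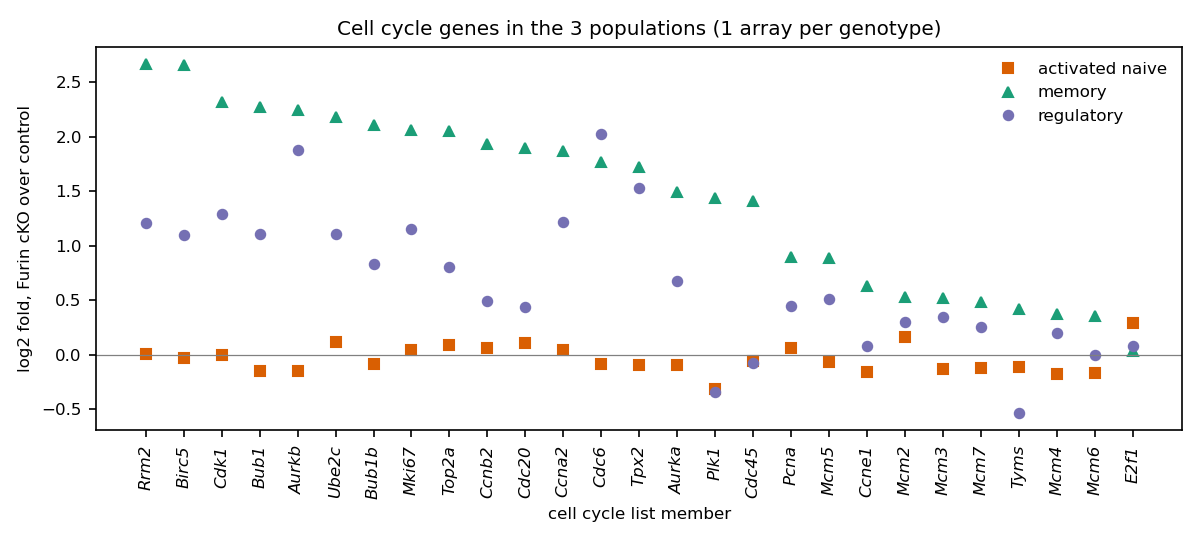
Log2 fold (Furin cKO over control, y axis) of the 27 measured cell cycle genes, ordered by their value in memory cells; squares are activated, triangles memory and circles regulatory cells, each from 1 array per genotype. All 27 lie above 0 in memory cells and 23 in regulatory cells, while the activated values run from -0.32 (Plk1) to 0.29 (E2f1).

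Regulatory cells on the array labelled Furin cKO carried more cell cycle and heat shock transcripts, and less of the immediate early genes Jun and Fos and of the cold-inducible RNA-binding protein gene Cirbp. Hsph1, a large chaperone of the HSP110 family, read 5036 against 1776, 2.84-fold higher. Cirbp read 719.7 against 2709, 3.76-fold lower, and Jun 209.5 against 814.5, 3.89-fold lower. Fos read 478.5 against 1427, although the immediate early list as a whole had a median of -0.06, inside its random range. Of 14590 genes measured, 458 were at least 2-fold higher and 309 at least 2-fold lower, with a scaled median absolute deviation of 0.33.

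Cell cycle genes were higher for 23 of 27 members, 10 of them at least 2-fold, with a median of 0.52 above all random lists. The replication licensing gene Cdc6 was 4.07-fold, Aurkb 3.68-fold, Tpx2 2.89-fold and Cdk1 2.45-fold higher, and Mki67 read 2396 against 1074.5; a further probe set of Tpx2 went the other way. On the same arrays granulocyte markers had a median of 1.01, above all random lists, with S100a8 2.32-fold and S100a9 2.19-fold higher. Stromal and epithelial markers had a median of 0.56 at percentile 99.4, with Epcam 1.60-fold higher, and were inside with the floor at the 20th percentile and at 0.33 with cyclic loess. Plasma cell markers had a median of -0.43 (-0.78 with quantile normalization), with Igha 2.21-fold lower, and erythroid markers a median of -1.44 over 3 members, each below the floor on 1 array. B cell markers (0.23) and myeloid and dendritic cell markers (0.05) lay inside their random ranges.

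Heat shock genes were higher for 8 of 9 members with a median of 0.63, above all random lists. Hspb1 was 2.26-fold, the constitutive chaperone gene Hspa8 1.60-fold and Hsp90aa1 1.59-fold higher, the last with another probe set lower. The inducible Hspa1a read 120.3 against 140.3. Unfolded protein response genes (0.12, led by Sdf2l1 at 1.41-fold and Hsp90b1 at 1.40-fold), follicular helper genes (0.11, led by Maf at 1.41-fold) and adhesion molecules (0.11) lay just above their random ranges, and cytokine receptors (-0.17, Ifngr2 1.49-fold lower) just below. Each of these 4 was inside with at least 2 of 7 alternatives. The Treg signature had a median of -0.07, inside its random range, and a mean of the opposite sign (0.01). Il2ra read 3702 against 4277, Ctla4 10619 against 11033 and Ikzf2 15968 against 13901. Foxp3 itself read 33.8 against 50.4, below and just above the floor, so that it could not be compared between the genotypes. TGF-beta ligand and response genes (0.02), convertase substrates (0.09) and type 1 effector genes (-0.11) were inside as well.

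Among single genes Rrp9, a factor of ribosomal RNA processing, was 6.30-fold, the netrin gene Ntn1 4.92-fold and the linker histone gene H1f4 3.86-fold lower. Another Ntn1 probe set had a log2 fold of only -0.13. The adaptor gene Dok3 was 3.80-fold, Mxd3 3.49-fold and the centromere guardian Sgo2a 3.14-fold higher, and the centriole gene Stil at least 4.29-fold. Of 37 lists 10 lay outside, against 1.85 by chance. With floors at the 60th and 20th percentiles 39 and 1757 genes were higher and 39 and 1450 lower. The excess of higher over lower genes was not kept by quantile normalization (260.0 higher and 259 lower) and shrank with cyclic loess (220.0 and 201).

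Whether the populations shared their differences was asked next. Memory and regulatory cells had 91 genes at least 2-fold higher in common, where independent lists of 726 and 393 among 13131 genes would share 21.7, and 28 lower, where 9.35 would be shared. The shared higher genes included Mki67, Cdk1, Birc5, Aurkb and Cdc6 of the cell cycle list, and S100a8, S100a9 and Camp of the granulocyte list. Activated and memory cells had 6 higher in common (1.56 for independent lists), among them Ifng, Ccl3 and Hspa1b, and 4 lower (1.09). Activated and regulatory cells had 2 and 1 (0.75 and 0.47). Across all genes the log2 folds correlated at 0.05 between activated and memory, at -0.00 between activated and regulatory and at 0.11 between memory and regulatory cells. With the floor at the 60th percentile memory and regulatory cells shared 19 higher and 2 lower, and with cyclic loess 59 higher and 26 lower. These counts rest on the memory labels. Furin read higher on the memory array labelled Furin cKO, but its probe set, of unknown position, cannot decide on the labels. An exchange of the genotype labels of the memory arrays was chosen after seeing the data. With it, memory and regulatory cells shared 22 higher (13.8 for independent lists) and 34 lower (14.8), with a correlation of -0.11. Activated and memory cells then shared 3 and 2 (1.15 and 1.48). Under the labels as given, these 22 and 34 genes went opposite ways in memory and regulatory cells. They too exceeded the numbers for independent lists, which are thus a low baseline. The 91 shared higher genes lay above both opposite counts. The 28 shared lower genes lay between them, but beside a smaller number for independent lists (9.35, against 13.8 and 14.8). The raw counts thus do not rank the shared lower genes against the opposite ones.

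At least 2-fold higher in all 3 populations was 1 of 10383 genes, the keratin-associated Krtap12-1, named after its values were seen (2.43-fold, 6.80-fold and 2.04-fold), and 0 were lower. Genes with 1 direction throughout included Hspa1b, an inducible HSP70 gene, with log2 folds of 1.18, 1.23 and 0.63 in activated, memory and regulatory cells, the cell cycle transcription factor gene E2f8 with 0.44, 1.84 and 1.55, and Rai14 with 0.80, 1.41 and 0.94. Downward these included Adh1 (-0.85, -1.33 and -0.72), Nucb2 (-0.50, -1.20 and -0.86) and Git1 (-0.64, -0.49 and -0.99). Probe sets of Rai14 disagreed in activated and memory cells.

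Averaged over the populations, limma called 0 genes higher and 0 lower in Furin cKO at an adjusted p of 0.05. The smallest adjusted p was 0.819, and 444 genes had an unadjusted limma p under 0.05. Evenly spread p-values would give 790.6. The other assignments of the arrays to the genotypes gave 422, 290 and 291, so 790.6 is a poor baseline for this fit. Furin itself had a log2 difference of 0.40 (SE 0.48, limma adjusted p = 0.836), higher in 1 of the 3 populations. Clone or predicted names aside, the smallest p belonged to Sdr42e1, with signals of 86.6 and 44.3 in activated, 97.3 and 17.5 in memory and 91.8 and 15.1 in regulatory cells. All 3 Furin cKO arrays lay below the floor for this gene. Close to it was Rilpl1, which was lower in 3 of 3 populations (log2 difference -0.91, SE 0.12, limma adjusted p = 0.819).

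The populations themselves differed widely. Against memory cells, limma called 2743 genes higher and 4260 lower in activated cells. The excess of lower genes rested on the scaling. Quantile normalization gave 3249 higher and 3071 lower, cyclic loess 3562 and 3236, and median centring 3473 and 3514. Il7r, the interleukin 7 receptor gene, was lower in activated cells (log2 difference -6.11, SE 0.18, adjusted p = 0.00173). Genes below the floor on the arrays of a population enter this fit at the floor, so that their difference is a lower bound. Such genes were S100a4, with 19.7 and 22.1 on the activated and 13169 and 17493 on the memory arrays, Ccr9, and Cth, which makes cysteine, with 4305 and 3870 (activated) and 5.9 and 6.6 (memory). Mki67 was 1.95 higher (SE 0.51, adjusted p = 0.0403). With a floor for each array, chosen after seeing the data, the genes lower numbered 8154.

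Between regulatory and memory cells limma called 0 genes either way, with a smallest adjusted p of 0.0518. At an unadjusted limma p under 0.05 were 3359 genes, against 790.6 for evenly spread p-values. The count of 0 sits at the threshold. It became 7 higher and 48 lower after median centring, 184 and 264 with the floor at the 60th percentile and 180 and 386 with a trended robust prior. Ctla4 (log2 difference 1.79, SE 0.14), Il2ra (2.20, SE 0.27) and Gpr83 (2.38, SE 0.20) were higher on both regulatory arrays, with limma adjusted p of 0.0518, 0.0720 and 0.0537. The tissue residency receptor gene Cxcr6 (-5.50) and the protease gene Ctsw (-3.84) were lower on both. Foxp3, the gene that defines regulatory cells and the sort, went against the label: its only probe set read 50.4 and 33.8 on the regulatory arrays and 1358 and 1116 on the memory arrays, control first. The other 17 measured members of the Treg signature had a median of 0.68 higher on the regulatory array in control cells, 17 of 17 being higher, and of 1.01 in Furin cKO cells, 16 of 17 being higher.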

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

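The results below differ between populations in opposite directions; with 1 array per genotype, the differences between populations were not tested. Each difference that involves memory cells rests on the genotype labels of the memory arrays. Furin read 647.4 on the control and 2203 on the Furin cKO memory array, but its probe set, of unknown position, cannot decide on these labels. With these labels exchanged, both populations of such a contrast would go the same way. The tests of the share of T cells and of cycling cells of another type were chosen after the result was seen.

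Cell cycle genes had medians outside their random ranges in opposite directions: the activated median lay 1.79 log2 units under the memory median (difference -1.79) and 0.58 under the regulatory median (-0.58), though the activated median itself was -0.07 and was inside its range with 3 of 7 alternatives. For memory cells, array scaling is argued against, since the lowest median under quantile normalization, median centring and cyclic loess was 1.81. Median centring shifts the list and the random lists nearly alike. The point thus rests on quantile normalization (1.83) and cyclic loess (1.81). A lower share of T cells with all other cell types raised alike is argued against as well, since it would raise both of 2 marker lists. Myeloid and dendritic cell markers had a median of -0.53, while granulocyte markers had 2.76. These values cannot decide on a lower share of T cells with a changed mix of other cells, in which some types rise and others fall. Cycling cells of another type in the CD4 and CD44 sort remain open, because T cell receptor signalling components had a median of -0.0286, inside the random range from -0.12 to 0.21, and B cell markers were higher for 8 of 11 members (6 at least 2-fold, median 1.12), among them Ms4a1 at 1285 against 297.4, with the abundant Ighm at 9365 against 12987. The genotype itself, differences between the animals behind 1 array each, and the unequal RNA or labelling quality of these arrays may account for the pattern and were not tested.

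NF-kB pathway genes stood above their range in activated and below it in memory cells, a difference of 0.66. Plasma cell markers stood above in memory and below in regulatory cells (1.20), as did their member Igha on its own (3.59). Follicular helper genes and unfolded protein response genes stood below in memory and above in regulatory cells, by -0.38 and -0.36. Jun was 6.20-fold higher in memory and 3.89-fold lower in regulatory cells, a log2 difference of 4.59. Zdhhc12 differed by 2.89 between activated and regulatory cells, Camta1 by 2.99 between activated and memory cells, and Creld1 by -2.96 between memory and regulatory cells.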

How the results depend on the processing

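The alternatives of a floor for each array and of exchanged memory labels were chosen after the data were seen; the others were planned. Of 1628 values of named genes under 7 alternatives, 1443 moved by less than the spread (SD) between probe sets of a gene, 185 moved by more, and 0 of the values past 2-fold changed sign. Under these 7 the correlations of log2 folds kept within 0.05 except between memory and regulatory cells, 0.0458 and 0.162 with floors at the 20th and 60th percentiles. Lists outside their ranges numbered 7 to 11 in activated, 13 to 16 in memory and 6 to 10 in regulatory cells, the 6 with the floor at the 60th percentile. All 7 alternatives kept the activated type 1, cytotoxic, cytokine, NF-kB and cholesterol lists, the memory cell cycle, type 1, cytotoxic, type 2, NF-kB, Treg, B cell, plasma cell, myeloid and granulocyte lists, and the regulatory cell cycle, heat shock, plasma cell and granulocyte lists outside, in the same direction. Furin cKO minus control gave 0 genes by limma in all 13 alternatives; the population term of this fit sets the arrays against each other within each population, and the labels give no replicate numbers for a further block.

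Counts of 2-fold genes moved with the floor by construction, since a lower floor admits dim genes. With the floor at the 20th percentile 472 were higher and 444 lower in activated, 2219 and 1531 in memory, and 1757 and 1450 in regulatory cells; shared were 117 and 82 between activated and memory, 88 and 67 between activated and regulatory, and 466 and 242 between memory and regulatory cells. With the floor at the 60th percentile these were 17 and 9, 258 and 221, and 39 and 39; shared were 3 and 1, 0 and 0, and 19 and 2, and regulatory minus memory gave 184 and 264 limma genes. With a floor for each array, activated cells had 122 and 92 and regulatory cells 259 and 145; shared were 15 higher between activated and memory, 4 lower between activated and regulatory and 14 lower between memory and regulatory cells. Limma then gave 66 and 151 genes for regulatory minus memory and 8154 lower for activated minus memory.

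With the genotype labels of the memory arrays exchanged, every memory fold turns its sign by construction; shared were then 3 higher and 2 lower between activated and memory and 22 higher and 34 lower between memory and regulatory cells, with correlations of -0.0461 and -0.108.

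For the following the cause was not tested. Cyclic loess gave 115 and 83 in activated and 220.0 and 201 in regulatory cells, with 16 higher and 7 lower shared between activated and memory, 4 lower between activated and regulatory and 59 higher between memory and regulatory cells. Quantile normalization gave 260.0 higher and 259 lower in regulatory cells and 3 lower shared between activated and regulatory. The mean of probe sets gave 22 lower in activated cells, 2 lower shared between activated and memory, 0 higher between activated and regulatory, 54 higher and 17 lower between memory and regulatory cells, and 35 and 81 limma genes for regulatory minus memory. Median centring gave 7 and 48 for that contrast and the trended robust prior 180.0 and 386. The depth of dim genes is limited by the floor, near which a signal cannot be told from background.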

Other observations

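The test of exchanged labels was chosen after its result was seen, and the heat shock factor target and innate-like T cell lists were written after related genes were seen. Heat shock genes beyond the list fixed at the start were also higher on the regulatory array labelled Furin cKO. Of 10 further targets of heat shock factor, 9 were higher, with a median log2 fold of 0.56 above all 10000 random lists; Chordc1 read 7239 against 3984, the co-chaperone gene Stip1 2632 against 1452 and Ahsa1 5240.2 against 3286. The same 10 genes had medians of -0.03 in activated and 0.08 in memory cells, inside their random ranges. Cirbp, which is induced by mild cold, read 719.7 against 2709 in regulatory cells, 2189 against 2893 in memory cells and 72.9 against 88.1 in activated cells, and was the only measured member of a list of 2 cold-inducible genes.

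A list of 10 genes of invariant NKT and other innate-like T cells had a median of -1.28 in memory cells, below all random lists, but that value rests on the members that led to the list: Zbtb16, Il17rb, Il4, Trgv1 and Trgv4 were between 3.29-fold and 5.54-fold lower. The other 5 had a median of -0.09, inside their random range, and went both ways, from Klrb1a at 76.9 against 137.0 to Plac8 at 24720.0 against 7247. In activated cells only 4 genes of the list were measured (Cd160, Tbx21, Slamf1 and Plac8), with a median of 0.51. The members that led to the list were not among them, and Tbx21 is also in the type 1 list. In regulatory cells the median was -0.31 over 10 genes. Both medians lay outside their random ranges. In activated cells interferon-stimulated genes had a median of -0.04, inside their random range, with 13 of 21 lower; Xaf1 was 2.37-fold lower and Irgm1 read 2167 against 1327. With the floor at the 60th percentile, which leaves 10 members, the median was 0.22 and lay above its range.

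Type 1 effector genes were higher on the activated array labelled Furin cKO. Array scaling is argued against, since the lowest median under quantile normalization, median centring and cyclic loess was 0.28 and stayed above the random range. Median centring shifts the list and the random lists nearly alike, so only quantile normalization (0.277) and cyclic loess (0.292) bear on this. Memory cells carried into the naive sort could bring Ifng and Nkg7, yet the 100 genes with the largest excess in control memory cells had a median log2 fold of 0.0037 in activated cells, inside the random range from -0.08 to 0.07. This does not exclude carried cells, although such a value had been set beforehand as the sign against them, because they would have been stimulated for 2 days as well and need not keep a fresh memory profile. The genotype, a different rate of differentiation in culture and differences between cultures stay open and were not tested.

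Foxp3 read lower on the regulatory than on the memory arrays. An exchange of memory and regulatory labels is argued against: the smaller of the genotypes' medians of the other Treg signature genes, regulatory minus memory, was 0.68, where an exchange needs values under 0. A Foxp3 transcript that the probe set does not read may account for it, for example from an altered allele used for sorting, which the labels do not describe. The annotation names only 1 Foxp3 probe set, so no further probe set decides this, and the question stays open.

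For genotype averaged over the populations, 4 assignments of the 2 arrays of each population to the genotypes exist, too few for a share under 0.05. Splits that put both arrays of a population in 1 group were not used, because the population term removes them. The real assignment gave 444 genes at an unadjusted limma p under 0.05, as many as 1 of the 4. The highest of the others, with the activated arrays exchanged, gave 422. With the memory arrays exchanged, the pair whose Furin signal was higher on the Furin cKO array, 290.0 genes passed, and with the regulatory arrays exchanged 291.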
